A study of Mus musculus with 12 samples.

How the data were processed

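CD45+/CD11b+/Ly6G- cells were sorted from paws of Flox and cKO mice 4 h after saline or 1% carrageenan, per the labels. Each of the 12 libraries pooled cells of 3 or 4 mice, per the labels, and the size of a single pool was read from the number range in its title. RNA was extracted with the PureLink Micro kit, and 3' mRNA libraries with unique molecular identifiers (Lexogen LUTHOR) were sequenced with paired-end reads on an Illumina NovaSeq, per the labels. Per the submitters' processing notes, cutadapt and STAR were used with the mouse genome GRCm38; versions, the roles of the tools, the read counter and its annotation are not given in the sources used here. The count tables deposited by the authors hold a signal in normalized counts, in which reads per gene were divided by 1 size factor per library, with saline and carrageenan normalized separately. Per the file headers, the authors' other tables give the log2 fold change of cKO over Flox with its standard error, for each treatment. Per the file headers, those tables also give a p-value per gene and an adjusted p-value. The column names are those of DESeq2, a tool that the sources used here do not name. How the fold changes were estimated is not stated. Several genes without an adjusted p had nearly the same standard error (in saline Rgs5 0.469, Hba-a2 0.468 and Kdm5d 0.468). The authors' fold changes thus need not share the scale of those computed here, and a smaller size is not read as a weaker effect.

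Whole reads were recovered from the deposited signal, because every value of a library was a whole multiple of 1 step (100% of low values, tolerance 0.001). Reads assigned to genes ranged from 111925 (Flox saline 1-3) to 2987015 (cKO saline 5-8), and genes with at least 1 read from 8384 (Flox saline 1-3) to 16225 (cKO saline 1-4). A single read equalled 5.46 normalized counts in the shallowest library and 0.268 in the deepest, so that 3 reads, taken as the floor over a group, stood for very different values. Mitochondrial genes held 1.98 to 4.60% of reads and entries that are not genes 0.170 to 2.23%, nearly all of them a 28S ribosomal RNA entry, left out of the comparisons with all 121 entries that are not genes. Of 55401 gene IDs, 55141 were matched to a symbol and placed on GRCm38 with the GENCODE vM21 annotation; where several IDs shared a symbol, the 107 other IDs carried their ID in the name. Libraries of a group were checked in pairs for a library entered more than once, and each pair differed by more than counting error (chi-square per degree of freedom 3.00 to 18.7).

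The main test was limma with a mean trend on log2 of the value plus 1, on genes with a value of at least 5 in at least 3 libraries, and an adjusted p (Benjamini-Hochberg) under 0.05. The added 1 can understate changes of genes with low values, and can enlarge them where a shallow library holds no read of the gene. Genotypes were compared within each treatment on the deposited scale (9371 genes in saline, 9151 in carrageenan). For carrageenan against saline within each genotype (10240 genes), all 12 libraries were put on 1 scale by medians of ratios over 6501 genes and fitted together. The difference between genotype effects (10243 genes) was fitted on all 12 libraries on the deposited scale, since each effect lies within 1 table. The plan named normalized counts, and limma on log2 values was kept although whole reads could be recovered; edgeR (quasi-likelihood, TMM) and DESeq2 on those reads were run as alternatives. DESeq2 gave no adjusted p for 2544 genes in saline and 7096 in carrageenan. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used.

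For the choice of test, the gene lists, the rule for named genes and the alternatives, choices were made before the data were examined, except where the text says otherwise. Of 39 fixed gene lists, those with at least 3 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison), which compares a list with all other genes. They were tested again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. A count adjusted over the list alone applies the Benjamini-Hochberg adjustment to the list's own limma p-values. The 9 lists described in every comparison were picked after a first look at the results, and every list that passed is given beside them.

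Named genes were Fabp5 and Lyz2 in every comparison, and, among genes past the threshold with groups that do not overlap and a mean of at least 20, the 10 largest rises and the 10 largest falls. Where fewer than 5 genes met this, the 10 with the smallest p were named. From each list described, up to 4 tested members with the smallest p were taken, and all changed members where 3 or fewer changed. The 5 genes with the smallest adjusted p in the authors' tables and the 10 with the smallest p for the difference of effects completed the rule. Gene models (Gm numbers, Rik names, names ending in -ps or -rs with a number) and IDs without a name were counted but not named. Lyz1 in saline, Hspb1 and the markers of single libraries were named outside the rule, after their values were seen.

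For a gene with 1 to 3 reads in a group, the ratio of pooled values is given as its 95% counting interval. Relations with depth used exact permutation tests. The alternatives were other pseudocounts (0.5 and 5), no filter or a mean of at least 20, TMM or deposited scaling, all 12 libraries in 1 model or only the 6 of a genotype, no trend, arrayWeights, edgeR, DESeq2, a 2-fold minimum, a replicate block, and leaving out each library in turn. limma-voom, thinning to the shallowest library, leaving out the pair of libraries apart from their groups, and leaving out each library for the correlation of genotype effects were added after seeing the data.

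The titles give saline and carrageenan libraries of a genotype the same mouse-number ranges, without saying whether the mice are the same. Pairing was checked by correlating the residuals of libraries with the same range across genes. They were 0.00905, -0.0182 and 0.109 in Flox, where not every pair lay above 0.1 and the numbers were taken not to pair the libraries. They were 0.200, 0.334 and 0.432 in cKO, where they were taken to pair them. The highest correlations with another range were 0.0299, 0.235 and -0.347 there. Reads ranked the cKO pools in the same order in both treatments, and the Flox pair at 0.109 was the deepest of its group in both. The correlations therefore cannot tell shared animals from shared depth. The labels do not settle the question, so the pairing in cKO is an assumption, and traits shared by pools other than the animals were not tested. The fit with a replicate block was an alternative, and its value is given where it changes a call. The tests were also run on simulated data. Of genes raised or lowered 4-fold, limma recovered 63.9% in saline, 72.8% in carrageenan, 74.7% and 76.0% for carrageenan in Flox and cKO, and 19.0% for the difference of effects. For 2-fold changes it recovered 4.67%, 7.33%, 10.0%, 6.33% and 0.667% in the same order (3 simulations each). In that order edgeR recovered 89.0%, 87.6%, 78.3%, 94.7% and 43.0% of 4-fold changes. For 2-fold changes edgeR recovered 14.3%, 12.0%, 10.3%, 21.0% and 2.67%. The changed genes were drawn from those with a mean of at least 20, so recovery at lower values was not covered. Many genes were changed at once (298 to 300 per fold over the 3 simulations), which eases the adjusted threshold. No simulated library was set apart from its group. Recovery may be lower where few genes change, so a count of 0 is no sign that 4-fold changes are absent.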

Results

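RNA was sequenced from CD45+/CD11b+/Ly6G- myeloid cells sorted from mouse hind paws 4 h after an intraplantar injection of saline or 1% carrageenan, a seaweed polysaccharide used to provoke acute inflammatory pain. The mice were FABP5Flox (here Flox) or FABP5Flox/LysM-Cre (here cKO), in which Cre recombinase is driven from the lysozyme M gene Lyz2 in myeloid cells. No group carried LysM-Cre alone. Effects of the Cre, of its Lyz2 allele and of targeting Fabp5 therefore cannot be told apart in cKO against Flox. Each of the 4 groups held 3 libraries (n = 3), and each library was a pool of 3 or 4 mice (10 mice per Flox group and 12 per cKO group by the number ranges in the titles). Reads assigned to genes were 111925, 294546 and 637238 in the Flox saline pools 1-3, 4-7 and 8-10. They were 1931668, 2987015 and 1145606 in the cKO saline pools 1-4, 5-8 and 9-12. In carrageenan they were 280541, 220463 and 994161 in the same Flox pool numbers and 2271231, 2627107 and 508407 in cKO. The cKO libraries thus held 4.99 times as many reads as the Flox libraries (geometric means, exact two-sided permutation p = 0.00866, 6 libraries against 6), so depth was confounded with genotype. That permutation treats libraries as independent, though those of cKO were taken as paired by mouse numbers. The share of reads on the 28S ribosomal RNA entry was 0.885 to 2.23% in Flox libraries and 0.170 to 1.06% in cKO libraries other than carrageenan 9-12, which held 2.13%. Mitochondrial genes held 1.98 to 3.11% in Flox and 2.36 to 4.60% in cKO. On principal components of all 12 libraries, the shallowest one (Flox saline 1-3) stood apart on the first axis at -190, against -7.14 to 32.1 for the others. The cKO carrageenan 9-12 library lay at 42.4 on the second axis, against -18.0 and -8.91 for the other cKO carrageenan pools.

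Fabp5, the targeted gene, encodes a fatty acid binding protein that carries lipids inside cells (ENSMUSG00000027533, chr3:10012548-10016607 on GRCm38). In saline it was read at 5.46, 36.5 and 23.9 normalized counts in the Flox libraries (1, 15 and 21 reads). The cKO libraries gave 6.36, 4.29 and 11.8 (18, 16 and 19 reads). In carrageenan the Flox libraries gave 43.1, 94.9 and 32.8 (17, 29 and 45 reads) and the cKO libraries 6.01, 11.1 and 22.3 (18, 39 and 15 reads). The carrageenan groups did not overlap (13.2 ± 8.34 against 56.9 ± 33.3, mean ± SD, cKO against Flox). The saline groups did (7.49 ± 3.89 against 21.9 ± 15.6). The log2 fold change of cKO over Flox was -2.06 ± 0.53 (± SE) in carrageenan and -1.20 ± 0.79 in saline, neither past the threshold over all genes (limma adjusted p = 0.497 and 0.683). Without the cKO carrageenan 9-12 library it was -2.50 in carrageenan with an adjusted p of 0.0346 (limma). That omission, also used below, leaves fewer cKO than Flox libraries, and the library had been seen to stand apart from its group. In saline the log2 fold change of Fabp5 was -1.94 without Flox saline 1-3, which held 1 Fabp5 read, and -0.68 without Flox saline 4-7. Fabp5 transcripts were therefore still counted in every cKO library, and the sources used here do not say whether the 3' end read by this protocol lies in the deleted part.

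Lyz2, the lysozyme gene that carries the Cre, was also lower in cKO cells (ENSMUSG00000069516, chr10:117277331-117282321). Its normalized counts in carrageenan were 2456 ± 816 against 5276 ± 723 (cKO against Flox, log2 fold change -1.14 ± 0.28, limma adjusted p = 0.497, no overlap). Without the cKO carrageenan 9-12 library the difference passed (-1.40, adjusted p = 0.00688). In saline they were 2939 ± 134 against 4514 ± 1401 (-0.57 ± 0.37, adjusted p = 0.683), with overlapping groups. The adjacent gene Lyz1 (ENSMUSG00000069515, chr10:117287797-117292868) encodes a related lysozyme, and its saline value is given because the gene stood out in carrageenan. Lyz1 was higher in every cKO library than in any Flox library of its treatment, at 575 ± 31.7 against 223 ± 21.8 in carrageenan (1.37 ± 0.21) and 1015 ± 228 against 442 ± 109 in saline (1.20 ± 0.29). Neither passed in limma (adjusted p = 0.497 and 0.683), and in carrageenan Lyz1 passed without the 9-12 cKO library (1.41, adjusted p = 0.00723). The ratio of Lyz1 to Lyz2 counts ranged from 0.0348 to 0.0538 in Flox carrageenan and 0.160 to 0.321 in cKO carrageenan. In saline it ranged from 0.0775 to 0.118 and from 0.245 to 0.414.

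**Figure D1:**
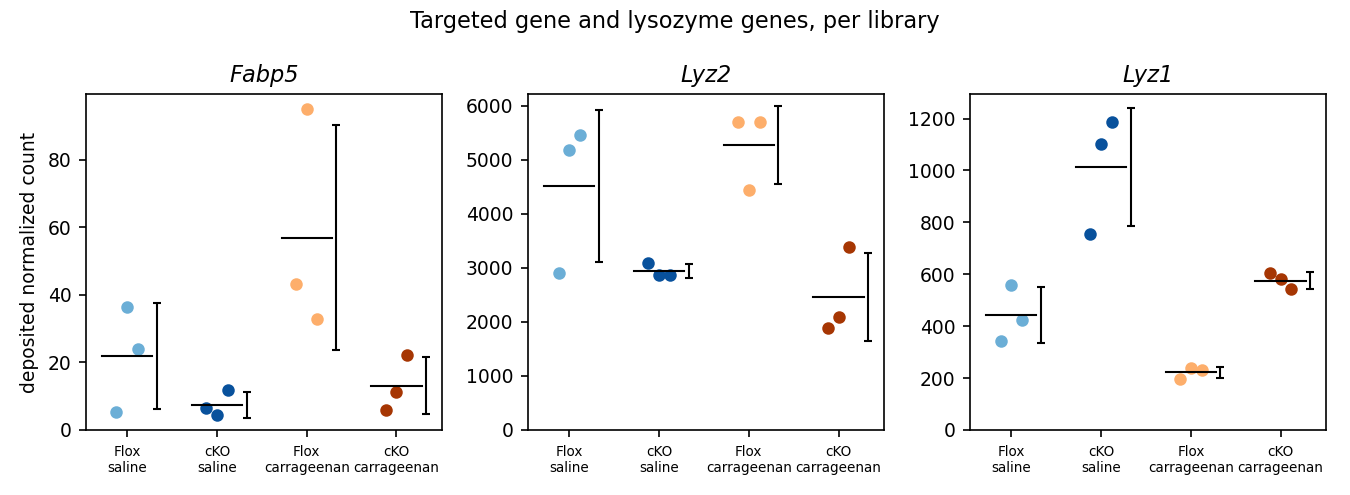
Fabp5, Lyz2 and Lyz1 in each library, in normalized counts as deposited; saline and carrageenan were normalized separately. Points are libraries (3 per group, each a pool of 3 or 4 mice), horizontal lines are means and error bars are SD.

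Carrageenan against saline in Flox cells asked what inflammation did in the sorted population with Fabp5 intact. Of 10240 genes tested, 735 changed, 453 of them higher in carrageenan and 282 lower (limma adjusted p under 0.05, 3 libraries against 3). Groups did not overlap for 732 of these; chance gives 10% of unselected genes, and selection by a small p favors separation. The acute-phase gene Saa3 rose from 2.57 ± 4.46 to 615 ± 148 normalized counts on a common scale (log2 fold change 8.19 ± 0.74 ± SE). Inhba, which encodes an activin subunit, rose from 2.57 ± 4.46 to 249 ± 88.6 (6.87 ± 0.88). Saa3 and Inhba lay near the floor in Flox saline, so their log2 values depend on the added 1 and are no exact measure of size. The chemokine Cxcl10 (6.20 ± 0.81), the calcium-binding alarmin S100a9 (6.16 ± 0.95), the immune checkpoint ligand Cd274 (5.71 ± 0.78), the antiprotease Slpi (5.66 ± 1.08), Ifit1 (5.57 ± 0.70) and Slfn4 (5.46 ± 0.96) rose as well. Ifit3 had 1 read in Flox saline and 220 in carrageenan (ratio interval 30.1 to 6722), and the cytotoxic granule gene Gzmb 1 and 106 reads (14.3 to 3255). Among the largest falls were the C-type lectin Cd209b (2.19 ± 1.99 against 50.7 ± 18.6, -4.23 ± 0.67), the interleukin-33 receptor Il1rl1 (-4.42 ± 0.94), and the lysophospholipid receptor Gpr34 (-4.02 ± 0.81). They also included Prune2 (-4.68 ± 0.88), Etv1 (-4.43 ± 0.65), Kank2 (-4.21 ± 0.79), Slc37a2 (-4.02 ± 0.70), Rasgrp3 (-3.88 ± 0.75) and Stard8 (-3.82 ± 0.92). Il1rl1 lost the call in 2 of 12 omissions of a library (adjusted p up to 0.0607), and Stard8 was at -2.39 without Flox carrageenan 1-3. Coro2b had 86 reads in saline and 2 in carrageenan (ratio interval 0.00213 to 0.0667). The count was 417 without Flox carrageenan 1-3 and 334 without Flox carrageenan 4-7. edgeR passed 615 genes and DESeq2 886. With the deposited scale 718 genes passed and the share of higher calls was 52.4% instead of 61.6%, as the median over all genes shifted by -0.085. Fabp5 itself was 60.5 ± 35.4 against 21.6 ± 15.2 (1.61 ± 0.70, adjusted p = 0.186) and Lyz2 5603 ± 765 against 4474 ± 1264 (0.36 ± 0.32, adjusted p = 0.519), neither past the limma threshold. Without Flox saline 1-3, with its 1 Fabp5 read, these log2 values were 0.87 and 0.076.

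Gene lists fixed before the data were examined described the Flox response, and 14 of the 36 tested shifted against all other genes (camera, preset correlation). Of 19 interferon-stimulated genes, 18 rose (19 adjusted over the list alone), with a median log2 fold change of 3.97. Oasl2, an antiviral synthetase homolog, went from 34.2 ± 3.17 to 226 ± 60.1 (2.66 ± 0.25). Cmpk2 went from 2 to 153 reads (ratio interval 16.0 to 491). This list passed at adjusted p = 4.42e-22, and was the only one to pass with an estimated correlation (adjusted p = 0.0484). Of 20 inflammatory cytokines and chemokines, 11 rose and 9 did not pass (14 adjusted over the list alone). Those that rose included Ccl5 (5.21 ± 0.41), Il1rn, the interleukin-1 receptor antagonist (4.57 ± 0.44), Ccl4 (4.28 ± 0.47) and Il6 (2.85 ± 0.32). For this list camera gave adjusted p = 1.47e-12 (adjusted p = 0.162 with an estimated correlation). Of 14 mediators known to sensitize nociceptors, 8 rose (9 up and 1 down adjusted over the list alone). Among them were Ptgs2, which encodes cyclooxygenase-2, from 50.8 ± 43.0 to 429 ± 27.3 (3.44 ± 0.50), Edn1 (4.88 ± 0.71) and Osm (2.90 ± 0.43). The list gave adjusted p = 1.48e-06, and adjusted p = 0.226 with an estimated correlation.

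Markers of resident macrophages went the other way in Flox cells: 11 of 18 fell and 7 did not pass (14 down and 1 up adjusted over the list alone), with a median of -1.36. The hemoglobin scavenger receptor Cd163 fell from 850 ± 129 to 216 ± 46.1 (-1.98 ± 0.24), the selenium carrier Selenop by 2.50 ± 0.38, the folate receptor Folr2 by 2.32 ± 0.40 and the transcription factor Maf by 1.70 ± 0.27. The list gave adjusted p = 3.84e-11, and 0.0568 with an estimated correlation. Beside this, 8 of 13 inflammatory monocyte markers rose (8 up and 1 down adjusted over the list alone), such as Ly6c2 (3.40 ± 0.55), Plac8 (3.21 ± 0.51), Vcan (3.71 ± 0.62) and Thbs1 (3.37 ± 0.57). So did 7 of 10 neutrophil markers, all 7 also adjusted over the list alone, such as Lcn2 (4.77 ± 0.81), S100a8 (4.78 ± 1.00) and Csf3r (2.66 ± 0.43). Ly6g itself, the marker the sort excluded, had 4 reads in all 12 libraries. These lists passed at adjusted p = 3.91e-06 and 6.23e-05 (camera; adjusted p = 0.259 and 0.226 with an estimated correlation). Of 12 hypoxia response genes 3 rose (7 adjusted over the list alone), namely Hif1a (1.70 ± 0.27), Egln3 (4.48 ± 0.80) and Adm with 2 and 21 reads (ratio interval 1.98 to 71.1). Of 16 glycolysis genes 5 rose (6 adjusted over the list alone), such as the glucose transporter Slc2a1 (2.39 ± 0.48), Hk2 (1.79 ± 0.39), Pfkp (1.49 ± 0.31) and Pkm (1.26 ± 0.28). Their lists gave adjusted p = 2.85e-05 and 7.74e-05 (adjusted p = 0.162 and 0.382 with an estimated correlation). Of 18 NF-kB target and feedback genes 5 rose (6 adjusted over the list alone), for example Sod2 (2.35 ± 0.30), Ikbke (1.90 ± 0.47), Ier3 (1.44 ± 0.36) and Bcl3 (1.12 ± 0.29). Over 12 omissions of a library Bcl3 and Ier3 lost the call in 5 (adjusted p up to 0.110 and 0.113) and Ikbke in 4 (0.0881). The list gave adjusted p = 0.0173, and adjusted p = 0.238 with an estimated correlation. It lost the call in 2 omissions (adjusted p up to 0.0936).

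The lists nearest to FABP5 lipid handling moved in mixed ways in Flox cells. Of 15 prostanoid synthesis and receptor genes, Ptgs2 rose, and the prostaglandin E synthase Ptges rose from 3 to 80 reads (ratio interval 6.78 to 102). Hpgd, which degrades prostaglandins, fell from 60.3 ± 17.2 to 6.94 ± 6.02 (-3.56 ± 0.78). It lost the call in 1 omission of a library (adjusted p = 0.0517), and was at -2.36 without Flox carrageenan 4-7. The other 12 did not pass (5 up and 2 down adjusted over the list alone; list adjusted p = 0.455). Of 16 PPAR target genes, the lipid droplet coat gene Plin2 rose (1.47 ± 0.30), while the fatty acid transporter Cd36 (-1.45 ± 0.28) and lipoprotein lipase Lpl (-2.02 ± 0.34) fell, and 13 did not pass (3 up and 3 down adjusted over the list alone). Plin2 lost the call without Flox carrageenan 4-7 (adjusted p = 0.0501). The PPAR median was 0.11 and the test direction was down (adjusted p = 0.763). Markers of other cells also differed by treatment in Flox: the collagen gene Col1a1 (3.08 ± 0.79) and the proteoglycan gene Dcn (2.07 ± 0.50) rose among 10 fibroblast markers (7 adjusted over the list alone). So did the endothelial genes Pecam1 (2.56 ± 0.69) and Kdr (1 and 17 reads, ratio interval 2.05 to 547) among 6 endothelial and mural markers (4 adjusted over the list alone). Both lists passed (adjusted p = 3.22e-04 and 0.00329; adjusted p = 0.345 and 0.259 with an estimated correlation). Ribosomal proteins (median 0.70, 0 of 22 past the limma threshold, Rplp0 1.12 ± 0.55), proliferation genes (-0.70, 0 of 12, Top2a -2.32 ± 0.86) and the tissue dissociation response (-0.36, 1 of 14, Fosb falling by 2.48 ± 0.42, 2 adjusted over the list alone) passed as lists at adjusted p = 0.00185, 0.0364 and 0.0499. With an estimated correlation these gave adjusted p = 0.628, 0.421 and 0.421. Leaving out single libraries, of 12, ended the call of ribosomal proteins in 1 case (adjusted p = 0.101, median 0.26), of proliferation genes in 2 (up to 0.108) and of the dissociation response in 5 (up to 0.171).

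**Figure D2:**
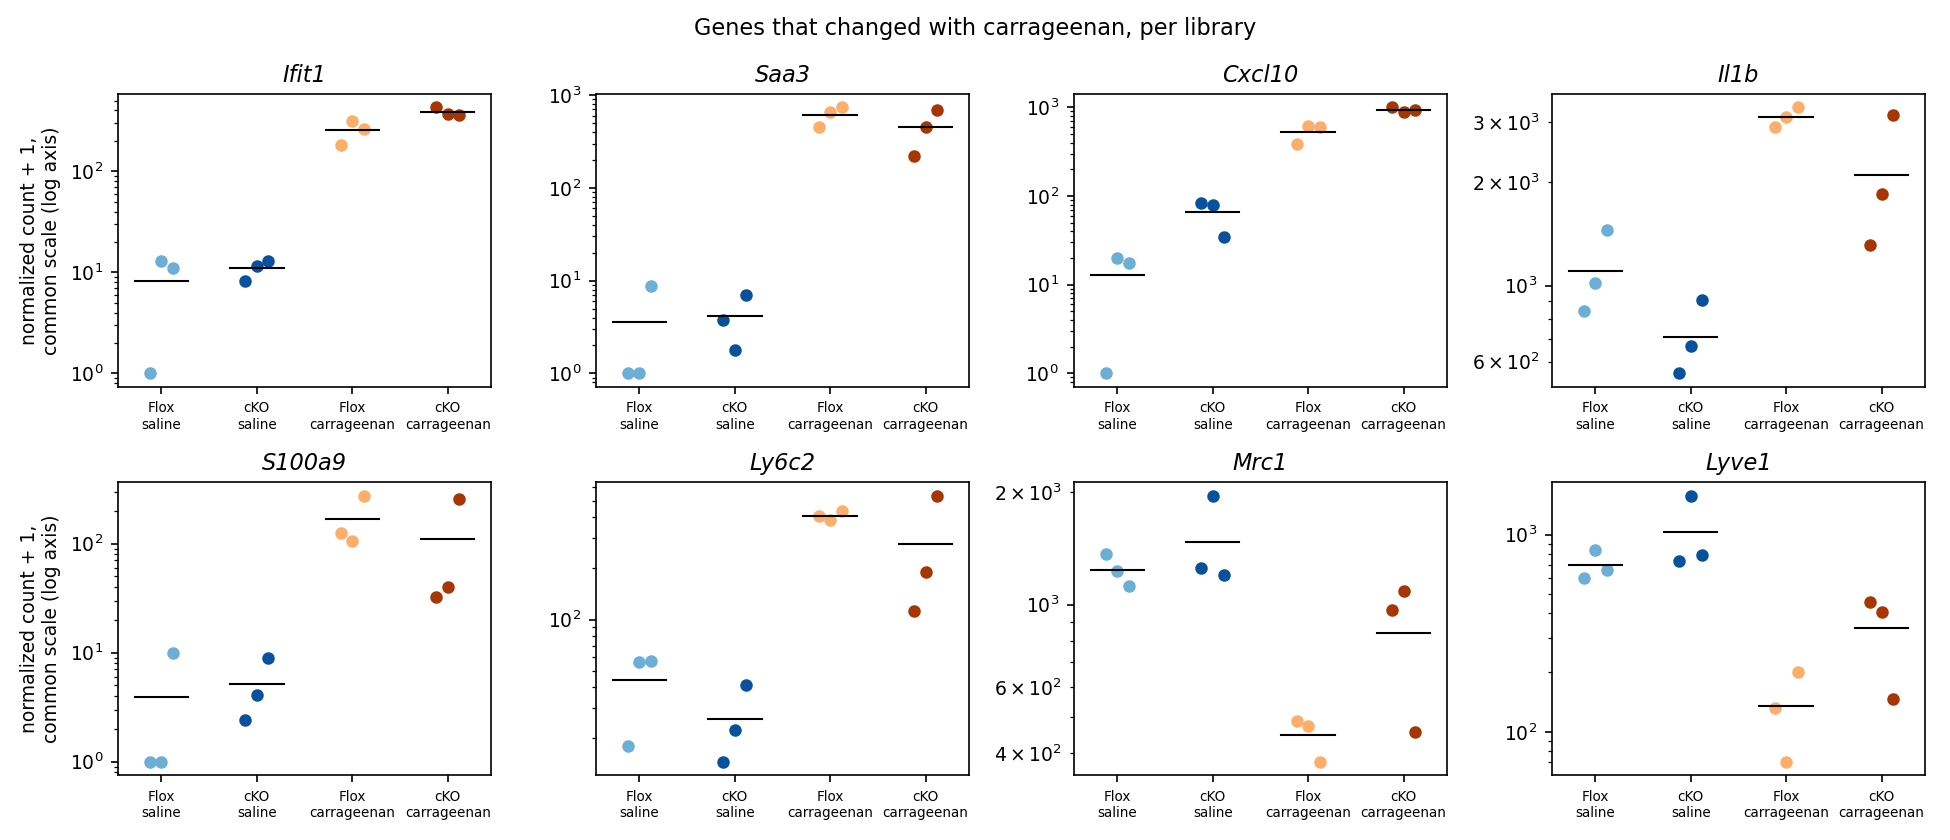
Genes that changed with carrageenan in at least 1 genotype, in normalized counts plus 1 on the common scale (log axis). Points are libraries (3 per group) and horizontal lines are means; no error bars are drawn.

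The same contrast in cKO cells asked whether the response persisted when Fabp5 was targeted. Of 10240 genes, 270 changed, 215 higher in carrageenan and 55 lower (limma adjusted p under 0.05), and groups did not overlap for any of the 270, which the selection favors as well (chance 10% of unselected genes). Saa3 rose from 3.21 ± 2.66 to 452 ± 232 (6.82 ± 0.74), and the antiviral gene Rsad2 from 13.2 ± 3.79 to 805 ± 208 (5.83 ± 0.70). So did Ifit2 (5.50 ± 0.76) and Ifit1 (5.16 ± 0.70), the nucleotide kinase gene Cmpk2 (4.75 ± 0.64), and Slfn4 (5.01 ± 0.96). The guanylate-binding gene Gbp5 (4.71 ± 0.74), the signaling lymphocyte receptor Slamf1 (4.74 ± 0.82), the pentraxin Ptx3 (4.70 ± 0.99) and the histamine-forming enzyme Hdc (4.61 ± 0.45) followed. The organic anion transporter Slco2b1 fell from 102 ± 18.6 to 12.7 ± 8.30 (-3.18 ± 0.59), as did Sesn1 (-3.11 ± 0.61) and the lectins Cd209f (-2.79 ± 0.66) and Clec10a (-2.49 ± 0.40). Others that fell were Arl11 (-2.61 ± 0.61), Kifc3 (-2.32 ± 0.53), Lyl1 (-2.23 ± 0.52), Tpcn1 (-2.23 ± 0.44), Akr1b8 (-2.15 ± 0.50) and Wwp1 (-2.13 ± 0.40). With the cKO libraries paired by mouse numbers (replicate block), Cd209f (adjusted p = 0.0583), Kifc3 (0.0640) and Akr1b8 (0.0625) no longer passed. In 5 to 8 of 12 omissions of a single library Cd209f, Arl11, Kifc3, Akr1b8 and Lyl1 lost the call (adjusted p up to 0.206), and in 1 to 4 Tpcn1, Ptx3, Sesn1, Slfn4, Slco2b1 and Wwp1 did. Fabp5 was 13.9 ± 8.89 against 7.31 ± 3.77 (0.77 ± 0.70, adjusted p = 0.925) and Lyz2 2599 ± 875 against 2871 ± 149 (-0.19 ± 0.32, adjusted p = 0.997). Without cKO carrageenan 9-12 these log2 values were 0.33 and -0.44, and without cKO carrageenan 1-4 they were 1.18 and -0.024. The count was 507 without Flox saline 1-3 and 84, 165, 111, 96 and 109 without cKO saline 1-4, cKO saline 5-8, cKO saline 9-12, cKO carrageenan 5-8 and cKO carrageenan 9-12. edgeR passed 733 genes and DESeq2 915. With the deposited scale the share of higher calls in cKO was 69.4% instead of 79.6%, as the median over all genes shifted by -0.108.

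In cKO cells 15 of 36 lists shifted (camera, preset correlation), and 6 held with an estimated correlation. Of those 6, 3 were interferon-stimulated genes (13 of 19 rose, 17 adjusted over the list alone, median 3.40, adjusted p = 6.58e-33), cytokines and chemokines (9 of 20 rose, 12 adjusted over the list alone, 1.72, adjusted p = 2.37e-19) and NF-kB targets (7 of 18 rose, 11 adjusted over the list alone, 1.07, adjusted p = 1.91e-13). The others were resident macrophage markers (3 of 18 fell, 13 down and 1 up adjusted over the list alone, -1.28, adjusted p = 2.25e-12), hypoxia genes (1 of 12 rose, 9 adjusted over the list alone, 1.54, adjusted p = 9.03e-11) and neutrophil markers (4 of 10 rose, 8 adjusted over the list alone, 2.68, adjusted p = 1.28e-09). With an estimated correlation they gave adjusted p = 0.00666, 0.0418, 0.00666, 0.0214, 0.0214 and 0.0418 in that order. Members that rose included Isg15 (4.25 ± 0.55), Mx1 (4.36 ± 0.53), Ccl5 (4.60 ± 0.41), Il1rn (4.06 ± 0.44), Ccl4 (3.68 ± 0.47), and Il6 (2.29 ± 0.32). So did the NF-kB subunit Nfkb2 (1.17 ± 0.25), its inhibitor Tnip1 (1.53 ± 0.34), Hif1a (1.98 ± 0.27), and the neutrophil genes S100a9 (3.96 ± 0.95), Lcn2 (3.83 ± 0.81), Csf3r (2.46 ± 0.43) and Mmp8 (3.60 ± 0.90). Of 12 omissions of a single library, Mmp8 lost the call in 9 (adjusted p up to 0.263), S100a9 in 8 (0.239), Lcn2 and Nfkb2 in 5 (0.134 and 0.0986) and Tnip1 in 4 (0.119). Cd163 (-1.38 ± 0.24), Maf (-1.52 ± 0.27) and Selenop (-1.62 ± 0.38) were the resident macrophage genes that fell. With the replicate block Selenop no longer passed (adjusted p = 0.0504), nor in 8 of the omissions. Over all alternatives Maf lost the call in 2 and Cd163 in 1. Of 14 nociceptor-sensitizing mediators 7 rose (8 up and 1 down adjusted over the list alone), with Ptgs2 at 373 ± 134 against 38.0 ± 10.5 (3.23 ± 0.50), Edn1 (3.60 ± 0.71) and Ptges (3.45 ± 0.72); Edn1 lost the call in 3 omissions and Ptges in 4. The list gave adjusted p = 1.28e-09, and adjusted p = 0.0673 with an estimated correlation. Of 13 inflammatory monocyte markers 6 rose, such as Ly6c2 (3.25 ± 0.55), Plac8 (3.52 ± 0.51) and Chil3 (3.42 ± 0.59), and 1 fell (8 up and 1 down adjusted over the list alone; adjusted p = 2.77e-09, adjusted p = 0.108 with an estimated correlation). Among prostanoid genes Ptgs2 and Ptges rose and 13 of 15 did not pass (2 up and 2 down adjusted over the list alone, adjusted p = 0.193 for the list). Among PPAR targets Cd36 (-1.14 ± 0.28) and Lpl (-1.54 ± 0.34) fell and 14 of 16 did not pass (1 up and 3 down adjusted over the list alone, adjusted p = 0.0808), with Plin2 at 1.00 ± 0.30. With the replicate block Cd36 no longer passed (adjusted p = 0.0583), nor in 10 of 12 omissions of a library, and Lpl did not in 5.

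The other lists that shifted in cKO cells lost the call with an estimated correlation. Glycolysis was 1 of them (2 of 16 rose, Slc2a1 2.17 ± 0.48 and Pfkfb3 1.66 ± 0.42, 6 adjusted over the list alone, adjusted p = 3.05e-07, adjusted p = 0.268 with an estimated correlation). So were mast cell and basophil markers (Hdc alone of 3, adjusted p = 0.00155, adjusted p = 0.0673) and mitochondrially encoded transcripts (0 of 7, median 0.68, mt-Co1 1.27 ± 0.51, adjusted p = 0.00237, adjusted p = 0.268). Endocannabinoid metabolism genes had a median of -0.88, and Abhd12, a lysophospholipid hydrolase, fell (-1.16 ± 0.26, 1 of 7, adjusted p = 0.00336, adjusted p = 0.0673 with an estimated correlation). In the leukotriene pathway the 5-lipoxygenase gene Alox5 fell (-1.44 ± 0.33, 1 of 7, 2 adjusted over the list alone, adjusted p = 0.0271, adjusted p = 0.358 with an estimated correlation). Fibroblast markers (median 1.01, 0 of 10, Dcn 1.10 ± 0.50, adjusted p = 0.0107) and ribosomal proteins (0.27, 0 of 22, Rpl10 0.86 ± 0.37, adjusted p = 0.0271) gave adjusted p = 0.435 and 0.650 with an estimated correlation. Over 12 omissions of a library, ribosomal proteins lost the call in 3 (median -0.14 without cKO carrageenan 9-12, adjusted p = 0.323), and fibroblast markers (0.0812) and leukotriene genes (0.0598) in 1 each.

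**Figure D3:**
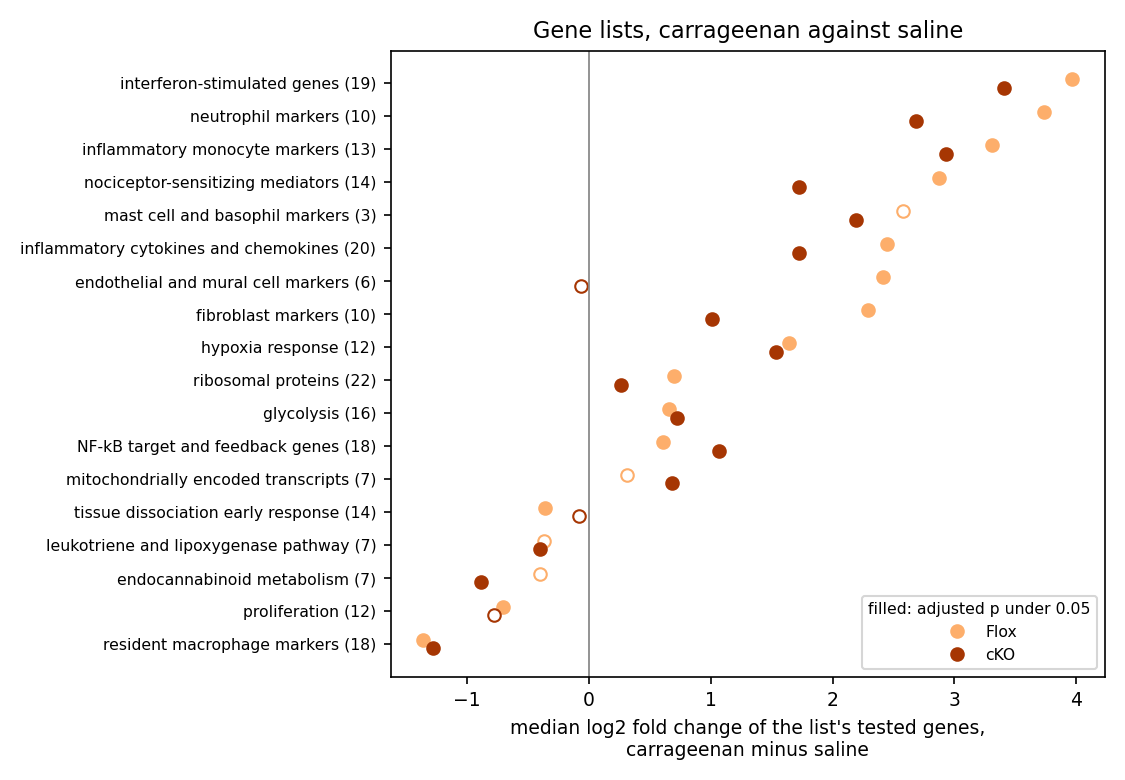
Median log2 fold change (carrageenan minus saline) of the tested members of each list that passed in at least 1 genotype, with the number of members tested in Flox in parentheses. Each point is 1 list in 1 genotype, from 3 libraries per group; filled points passed camera with the preset correlation, and no error bars are drawn.

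Set side by side, the responses shared 172 higher genes (9.51 expected if independent) and 45 lower genes (1.51 expected), with 0 called in opposite directions. Of the 788 genes called in either genotype, 774 had the same sign in both. Effects over all 10240 genes had a Pearson r of 0.622 and a Spearman rho of 0.526 across genes, which are not independent replicates. Ccl5 and Cd163 illustrate this, at 5.21 and -1.98 in Flox and 4.60 and -1.38 in cKO. The genotypes differed in the number of called genes, but the order depended on the tool (735 and 270 in limma, 615 and 733 in edgeR, 886 and 915 in DESeq2, Flox first). The test of the difference between the effects passed 0 of 10243 genes in limma (244 at an unadjusted p under 0.05), 0 in edgeR (233 unadjusted) and 0 in DESeq2. Fabp5 gave a difference of -0.86 ± 1.00 and Lyz2 of -0.58 ± 0.46 (limma adjusted p = 0.967 for both). Without Flox saline 1-3 they were -0.11 and -0.29, and Fabp5 was at -1.38 without Flox saline 4-7. The 10 genes with the smallest p, none past the threshold (adjusted p = 0.967), were Cutc, Adh7, Gzma, Cd2, Zfp574, Atxn2l, Hcar2, Nup153, Rfx3 and Lrp4. All but Atxn2l and Nup153 had 0 to 3 reads in Flox saline, so no size of the difference is given for them. Atxn2l, a stress granule gene, was 143 ± 19.7 in Flox saline, 82.4 ± 22.7 in cKO saline, 83.2 ± 15.9 in Flox carrageenan and 113 ± 20.4 in cKO carrageenan (1.26 ± 0.39). Nup153, of the nuclear pore, was 49.5 ± 14.8, 23.1 ± 13.5, 18.7 ± 16.9 and 40.2 ± 5.21 in the same order (2.57 ± 0.80).

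The genotypes in saline, the resting comparison, differed in no single gene past the threshold: 0 of 9371 passed in limma (508 at an unadjusted p under 0.05), 0 in edgeR (669 unadjusted) and 23 in DESeq2 (4 higher in cKO and 19 lower). Each of the 10 named genes with the smallest p had groups that did not overlap (limma adjusted p = 0.683 for all), and all 10 passed in DESeq2 (adjusted p from 0.00331 to 0.0365) and with arrayWeights (0.00123 to 0.0488). Higher in cKO were the heat shock genes Hsph1 (194 ± 76.3 against 40.0 ± 15.7, 2.26 ± 0.43) and Hspa1b (3280 ± 1258 against 628 ± 497, 2.57 ± 0.55; ENSMUSG00000090877, chr17:34956436-34959238). So was the aminopeptidase Npepps (78.9 ± 25.5 against 19.4 ± 7.96, 2.00 ± 0.45). Lower were the pyrin gene Mefv, an inflammasome sensor (34.3 ± 4.85 against 118 ± 44.9, -1.70 ± 0.33), and ferritin light chain Ftl1 (324 ± 72.9 against 776 ± 156, -1.26 ± 0.28). So were Rpl10 (-1.26 ± 0.26), Rpl29 (-2.01 ± 0.43), the histone genes H2afz (-1.65 ± 0.35) and H3f3a (-1.43 ± 0.31), and Mir703 (-1.73 ± 0.38). In the deposited table of the authors, 20 genes passed in saline (5 higher, 15 lower), and all 20 had the same sign here. Pseudogenes aside, its smallest adjusted p-values were those of Hsph1 (1.85, SE 0.37, adjusted p = 0.00188), Mefv (-1.49, SE 0.32, 0.00608), Hspa1b (1.83, SE 0.39, 0.00608), Rpl10 (-1.18, SE 0.26, 0.0106) and Ftl1 (-1.16, SE 0.26, 0.0106). Fabp5 stood at -1.10 (SE 0.45, adjusted p = 0.516). The heat shock genes and depth were both higher in cKO libraries and the 28S share lower in most. Simulations at these depths changed many genes at once, all with a mean of at least 20. There limma recovered 4.67% of log2 fold changes of 1. With edgeR the share was 14.3%.

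**Figure D4:**
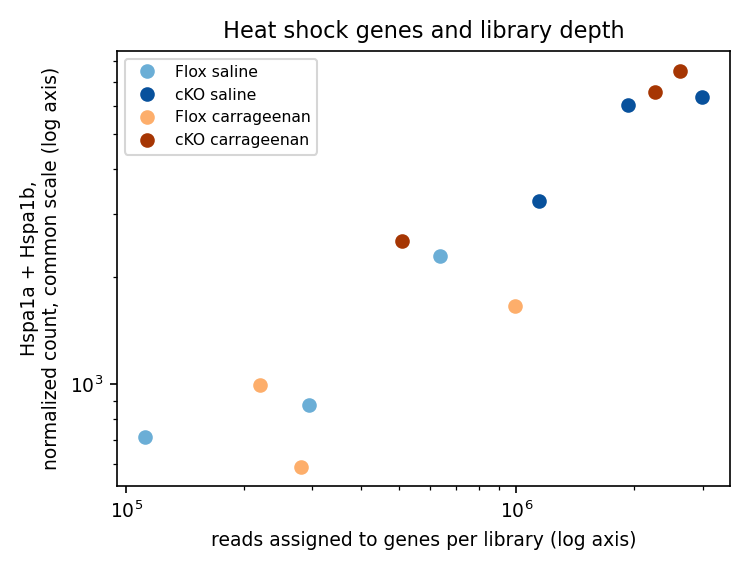
Summed normalized counts of Hspa1a and Hspa1b on the common scale against reads assigned to genes, both on log axes. Each point is 1 library (12 in all, colored by group); no error bars are drawn.

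Of 30 lists tested in saline, 6 shifted in camera with the preset correlation, and 0 with an estimated correlation or in fry. NF-kB target and feedback genes were lower in cKO for 14 of 18 members, 4 of them past the threshold adjusted over the list alone. Those were Nfkbie, an inhibitor of NF-kB (97.3 ± 8.01 against 185 ± 5.57, -0.92 ± 0.22), Nfkb2 (114 ± 15.7 against 208 ± 28.9, -0.86 ± 0.24), Tnip1 (-1.18 ± 0.33) and Traf1 (-1.32 ± 0.40). The list gave adjusted p = 1.40e-07, and adjusted p = 0.0950 with an estimated correlation. Ribosomal proteins were lower for 17 of 22 (median -0.29, 1 adjusted over the list alone, adjusted p = 2.01e-04, adjusted p = 0.768 with an estimated correlation). The 28S share was 0.885 to 1.92% in Flox saline and 0.170 to 1.06% in cKO saline. Dendritic cell markers were lower for 7 of 10, such as Cd209a (-0.62 ± 0.27) and Irf4 (-0.59 ± 0.22) (adjusted p = 0.00817, adjusted p = 0.749 with an estimated correlation). Neutrophil markers had a median of -0.78 over 4 members, with Il1r2 at 82.0 ± 40.9 against 262 ± 180 (-1.58 ± 0.60) and Retnlg at -2.52 ± 0.85. Csf3r (0.02 ± 0.60) and Trem1 (0.20 ± 1.15) turned sign under other settings (adjusted p = 0.0373, adjusted p = 0.749 with an estimated correlation). Without Flox saline 8-10 the median of the neutrophil list was 0.42 over 3 members (adjusted p = 0.531). Markers of skin and vessel cells were higher in the cKO saline libraries: 9 of 9 keratinocyte markers (4 adjusted over the list alone), such as Krt10 (456 ± 208 against 167 ± 79.0, 1.47 ± 0.44) and Krt14 (264 ± 84.0 against 121 ± 27.7, 1.09 ± 0.31). So were 4 of 4 endothelial and mural markers, such as Rgs5 (2.93 ± 1.04). These 2 lists gave adjusted p = 2.01e-04 and 0.0157, and 0.749 each with an estimated correlation. The 9 listed endothelial and mural genes held only 1009 reads in all libraries, so the added 1 and the shallower Flox libraries may weigh on their values. The authors' table gave Rgs5 0.94 (SE 0.47) without an adjusted p, by an estimate that need not share the limma scale. In carrageenan 1 of 5 of these markers was higher. Fibroblast (6 of 6) and erythroid markers (3 of 3) were also higher in saline, without passing. Without Flox saline 4-7 the number of shifted lists was 2. Over 6 omissions of a library, ribosomal proteins (adjusted p up to 0.156) and dendritic cell markers (0.103) lost the call in 2 each, and endothelial and mural markers in 1 (0.173) of the 3 that left enough members to test. Neutrophil markers lost it in 4 of the 6 (camera adjusted p up to 0.531).

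The remaining lists of interest did not pass in saline with all libraries, and 0 of their members passed in limma, also adjusted over the list alone. The median log2 fold change over all genes in saline was 0.25, so a count of higher members is no sign of a shift by itself. Cytokines and chemokines were higher in cKO for 16 of 19 (adjusted p = 0.156), with Cxcl10 at 66.0 ± 27.6 against 12.2 ± 10.6 (past the threshold in DESeq2, adjusted p = 0.0490), Ccl4 at 351 ± 117 against 138 ± 103 and Tnf at 443 ± 71.9 against 280 ± 177. That list passed without Flox saline 8-10 (median 0.81, adjusted p = 0.00793) and without cKO saline 1-4 (0.62, 0.0155). PPAR targets were higher for 14 of 16 (adjusted p = 0.158), with Plin2 at 223 ± 20.2 against 139 ± 37.8. Prostanoid genes had a median of 0.21 and a test direction of down (adjusted p = 0.626), with the prostaglandin receptor Ptger4 at 1.56 ± 0.82 and the synthase Ptges3 at -0.74 ± 0.26. Resident macrophage markers were higher for 14 of 18 (adjusted p = 0.319; C1qc 0.67 ± 0.35) and inflammatory monocyte markers lower for 7 of 13 (adjusted p = 0.0720; Plac8 -0.94 ± 0.53). The monocyte list passed without Flox saline 1-3 (median -0.45, adjusted p = 3.77e-04) and without cKO saline 9-12 (-0.17, 0.0140). Interferon-stimulated genes were higher for 12 of 16 (adjusted p = 0.784; Irf1 0.87 ± 0.42, Isg15 -1.08 ± 0.54) and nociceptor-sensitizing mediators higher for 7 of 10 (adjusted p = 0.626; Igf1 0.93 ± 0.54, Il1b -0.60 ± 0.32). Without Flox saline 1-3, the shallowest library, the log2 fold change was 1.70 for Cxcl10, 0.96 for Ccl4, 0.42 for Tnf, 0.48 for Ptger4, 0.21 for Igf1, 0.36 for C1qc and 0.51 for Irf1. Plac8 was at -0.52 and Isg15 at -0.68 without cKO saline 1-4, and Il1b at -0.36 without Flox saline 8-10.

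In carrageenan, where the genotypes were compared in inflamed tissue, 0 of 9151 genes passed in limma (897 at an unadjusted p under 0.05). In edgeR 0 passed (945 unadjusted) and in DESeq2 10 did (9 higher in cKO and 1 lower). Without the cKO carrageenan 9-12 library 420 passed in limma, 127 higher and 293 lower. Passes without that library are no separate support, since it was singled out for lying apart from its group. The 10 named genes with the smallest p had groups that did not overlap (limma adjusted p = 0.497 for all). Beside Lyz1, higher in cKO were the monocyte chemoattractant Ccl8 (212 ± 71.3 against 65.7 ± 16.3, 1.65 ± 0.31; ENSMUSG00000009185, chr11:82115185-82116799) and the B cell chemoattractant Cxcl13 (136 ± 29.9 against 52.4 ± 18.2, 1.40 ± 0.33). So were Hspa1b (3346 ± 1771 against 530 ± 284, 2.61 ± 0.50) and Hspa1a (1911 ± 762 against 487 ± 219, 1.97 ± 0.40; ENSMUSG00000091971, chr17:34969190-34972156), heat shock genes nearly identical in sequence. Others were the electron carrier Cyb5a (102 ± 33.2 against 33.3 ± 10.9, 1.57 ± 0.35), the sialyltransferase St6gal1 (1.81 ± 0.42), Sh3tc1 (1.41 ± 0.31) and the lysosomal peptidase Tpp1 (1.38 ± 0.33). The granzyme gene Gzma, of cytotoxic lymphocytes, was lower (4 reads in cKO and 35 in Flox, -3.90 ± 0.79). Without the 9-12 cKO library Ccl8 (1.92, adjusted p = 0.0102), Cxcl13 (1.58, 0.0375), Hspa1b (3.18, 0.00808), Hspa1a (2.37, 0.0108) and Gzma (-3.72, 0.0390) passed. So did Cyb5a (1.88, 0.0173), St6gal1 (1.98, 0.0482), Sh3tc1 (1.53, 0.0390), Tpp1 (1.64, 0.0249) and Hsph1 (2.34, 0.00704). The deposited table of the authors passed 5 genes, all higher in cKO: Lyz1 (1.29, SE 0.21, adjusted p = 3.29e-06), Hspa1b (2.08, SE 0.37, 7.14e-05), Hspa1a (1.65, SE 0.34, 0.00177), Ccl8 (1.43, SE 0.31, 0.00688) and Hsph1 (1.56, SE 0.37, 0.0252; here 215 ± 114 against 56.0 ± 15.7, 1.77 ± 0.45). It gave Fabp5 -1.52 (SE 0.41, adjusted p = 0.0997).

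Of 32 lists tested in carrageenan, 7 shifted between genotypes with the preset correlation in camera, and 0 with an estimated correlation or in fry. Resident macrophage markers were higher in cKO for 15 of 18 members (median 0.53), such as the complement gene C1qc (917 ± 362 against 405 ± 88.7, 1.11 ± 0.33), Selenop (893 ± 420 against 345 ± 84.2, 1.27 ± 0.38), C1qb (1.15 ± 0.35) and Folr2 (1.33 ± 0.46). Inflammatory monocyte markers were lower for 13 of 13 (median -0.44), such as Hp (-1.51 ± 0.63) and Ly6c2 (263 ± 212 against 383 ± 23.4). Neutrophil markers were lower for 9 of 9, such as S100a8 (52.7 ± 76.7 against 79.1 ± 40.1, -1.67 ± 0.93) and Il1r2 (-0.60 ± 0.28). The lists gave adjusted p = 0.00300, 7.24e-04 and 0.00293 (adjusted p = 0.634, 0.693 and 0.634 with an estimated correlation). Of their members 0 passed in limma, also adjusted over the list alone. Without the cKO carrageenan 9-12 library C1qc (1.49, adjusted p = 0.0102), Selenop (1.73, 0.00983), C1qb (1.51, 0.0219), Folr2 (1.80, 0.0443), Hp (-2.39, 0.00966), Ly6c2 (-1.47, 0.0163) and S100a8 (-2.98, 0.0174) passed over all genes. That library lay nearer to Flox in these same genes, so their passing without it is circular and no support. Without cKO carrageenan 1-4, Hp was at -0.83, Ly6c2 at -0.35 and S100a8 at -0.84, and the monocyte list no longer passed (median -0.15, adjusted p = 0.0891). The neutrophil list no longer passed without Flox carrageenan 8-10 (median -0.57, adjusted p = 0.0980), and Il1r2 was at -0.33 without cKO carrageenan 9-12. Within cKO the 9-12 library differed from the others in these genes: Ly6c2 was 535 in it, 150 in the mean of the other cKO pools and 407 in Flox. Folr2 was 82.1, 223 and 68.2 in that order, on the common scale. Ribosomal proteins were lower for 22 of 22 (median -0.75, Rps14 -0.78 ± 0.27, Rps18 -1.38 ± 0.49) and nuclear oxidative phosphorylation genes for 23 of 30 (median -0.41, Ndufs3 -1.30 ± 0.46). Of 6 mitochondrially encoded transcripts 5 were higher (mt-Nd4 9728 ± 2673 against 5607 ± 490, 0.76 ± 0.29). In carrageenan the 28S share was 1.51 to 2.23% in Flox and 0.341, 0.425 and 2.13% in cKO. These 3 lists gave adjusted p = 1.47e-09, 2.13e-04 and 0.0314, with adjusted p = 0.634 for each with an estimated correlation. The tissue dissociation response was higher for 10 of 14 (3 adjusted over the list alone: Hspa1a, Hspa1b and Jun, 387 ± 73.6 against 233 ± 17.4, 0.71 ± 0.23; adjusted p = 0.0312, adjusted p = 0.634 with an estimated correlation). Over 6 omissions of a library the dissociation response lost the call in 2 (adjusted p up to 0.118) and the mitochondrial transcripts in 1 (0.638).

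Among mediators of inflammation and pain, none passed over all genes between the genotypes in carrageenan in limma; the chemokines Ccl8 (1.64, adjusted p = 0.00468) and Cxcl13 (1.34, 0.0449) passed in DESeq2, and Ccl8 in the authors' table. With arrayWeights both passed, as did Ccl7, Ccl4, Cxcl10, Il10, Igf1, Il1b, Ptger4 and Tnip1 (adjusted p from 0.0339 to 0.0353). Igf1, a growth factor, was 142 ± 45.6 against 62.9 ± 10.5 (1.13 ± 0.29) and passed adjusted over the list alone among 14 nociceptor-sensitizing mediators. Il1b was at -0.65 ± 0.31 and Osm at -0.51 ± 0.29 (list adjusted p = 0.799). Without the 9-12 cKO library these passed over all genes: Igf1 (1.27, adjusted p = 0.0476), Il1b (-0.98, 0.0215), Ccl7 (1.26, 0.00808), Ccl4 (1.33, 0.00704), Ptger4 (1.70, 0.0417) and Tnip1 (-1.29, 0.0295). Without cKO carrageenan 1-4, Il1b was at -0.36, Osm at -0.25, Lpl at 0.56 and Ptger4 at 0.80. Of 20 cytokines and chemokines 12 were higher, such as Ccl7 (1631 ± 504 against 805 ± 99.0, 0.97 ± 0.28), Cxcl10 (888 ± 59.6 against 499 ± 117, 0.86 ± 0.24), Ccl4 (1.00 ± 0.31) and the anti-inflammatory Il10 (92.1 ± 25.7 against 42.9 ± 14.5, 1.11 ± 0.35). As a list they gave adjusted p = 0.291, with 0 adjusted over the list alone. Of 15 prostanoid genes 9 were higher, with Ptger4 at 77.5 ± 44.0 against 30.2 ± 10.3 (1.21 ± 0.46; list adjusted p = 0.904). Of 16 PPAR targets 10 were higher, with Lpl at 0.88 ± 0.39 and Acaa2 at 11.4 ± 3.02 against 24.5 ± 9.60 (median 0.08, test direction down, adjusted p = 0.983). NF-kB targets were lower for 10 of 18 (Tnip1 -0.94 ± 0.34, list adjusted p = 0.438). Interferon-stimulated genes were higher for 10 of 19, with Ifit1 at 0.65 ± 0.25 (median 0.08, mean -0.06, test direction down, adjusted p = 0.904). In none of these last 4 lists did a member pass adjusted over the list alone. Genotype effects in saline and carrageenan had a Pearson r of 0.322 across 8657 genes, and 63.6% of genes had the same sign. They share no library, but the cKO libraries were taken as paired by mouse numbers, so part of both values may come from shared pools. Depth was confounded with genotype (4.99 times as many reads in cKO) and cannot be told apart from it here. The medians over all genes, 0.25 in saline and 0.095 in carrageenan, also raise the share with the same sign.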

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

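The tests chosen after the result was seen were the relation of heat shock genes with depth within each genotype, the direction test for reads shared by Lyz1 and Lyz2, the Lyz1 to Lyz2 ratio of the cKO carrageenan 9-12 library, and the monocyte markers against neutrophil carry-over. All patterns weighed here were noticed in these data. Ptges3 had log2 carrageenan effects of opposite sign, -0.38 in Flox and 0.51 in cKO, with groups that did not overlap in either genotype. Lrp4 (2.28 in Flox and -1.11 in cKO) and Rfx3 (2.18 and -0.97) showed the same separation, with 1 and 2 reads in Flox saline (the ratio interval of carrageenan over saline in Flox was 0.826 to 273 for Lrp4 and began at 0.717 for Rfx3). Among genotype effects, Adh7 (2.46 in saline and -0.78 in carrageenan) and Cd2 (1.89 and -1.94) did, with 0 and 2 reads in Flox saline (ratio interval of cKO over Flox in saline for Cd2 1.18 to 38.3). The log2 values of these 4 genes that rest on Flox saline are set largely by the added 1 and are no measure of size. These reversals by separation were not tested as such, and the limma test of the difference of effects passed none of them (adjusted p = 0.967). Lrp4, Rfx3, Adh7 and Cd2 were looked at because they were among the 10 genes with the smallest p for that difference, so a count expected by chance does not apply to them. The 28S ribosomal RNA entry, which no comparison used, held 0.170% of reads in cKO saline 5-8 (5076 reads) and 2.23% in Flox carrageenan 1-3 (6394 reads).

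Hspa1a, Hspa1b, Hsph1 and Hspb1, which encode chaperones induced by heat and cell stress, were higher in cKO libraries of both treatments, and these libraries were also deeper. Thinning all libraries to 111925 reads left 90.1% of the mean log2 difference of the 4 genes. Random thinning keeps the ratio of well-counted genes on average, so this value could hardly fall and does not decide on counting depth. Within genotypes the summed Hspa1a and Hspa1b level went with depth, with Pearson r = 0.781 in Flox (rho 0.657, exact permutation p = 0.0681 and 0.175) and r = 0.955 in cKO (rho 0.829, exact permutation p = 0.0125 and 0.0583; adjusted over 2 relations 0.0250 and 0.117). These permutations treat libraries as independent, though those of cKO were taken as paired by mouse numbers. Without the 2 libraries farthest in depth r was 0.822 in Flox but 0.434 in cKO. In cKO those were saline 9-12 and carrageenan 9-12 (1145606 and 508407 reads). The cKO relation thus rests on pools of the same mouse numbers, 1 of which stood apart from its group. A difference in handling or yield that travels with depth is a candidate explanation for part of the heat shock difference. At equal depth the log2 difference was 0.92 (SE 0.36) instead of 2.24, and an effect of genotype on these genes stays open as well.

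Lyz1 was higher and Lyz2 lower in cKO libraries of both treatments. A fixed misplaced share of Lyz2 reads is argued against, since it would lower Lyz1 with Lyz2, while the Lyz1 difference lay at least 4.07 standard errors above 0. That direction was part of the pattern as noticed, so it is no separate test. A misplaced share that differs between the genotypes stays open. The first form of this test was undecided, since 19.1% of 50-base windows at the end of Lyz1 also occur in Lyz2, and the direction was then used instead. A change along the whole chromosome segment is argued against by 9 tested neighbours within 1 Mb, whose median absolute log2 difference (0.25) lay at percentile 3.94 of random lists, although 6 of the 9 had the sign of Lyz1 in both treatments. Thinning kept 99.2% of the difference, but it keeps the ratio of well-counted genes on average, so it does not decide on counting depth. The Cre insertion that the design places in Lyz2 may account for the lower Lyz2, and a strain variant carried with it that acts on Lyz1 stays open, both untested.

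The cKO carrageenan 9-12 library stood apart from the other cKO carrageenan pools in monocyte and neutrophil genes. In it 22 of 23 markers were higher (median log2 difference 1.36), such as Ly6c2 (535 against 150), Chil3 (523 against 112) and S100a8 (150 against 8.93), and resident macrophage markers had a median of -0.38. A wrong genotype label is argued against by its Lyz1 to Lyz2 ratio of 0.160, above 0.108, which is double the highest Flox carrageenan ratio. It was still the lowest of the 6 cKO ratios, and partial mixing stays open. Thinning kept 99.5% of the difference, but it keeps the ratio of well-counted genes on average, so it does not decide on depth. Carry-over of Ly6G-positive neutrophils alone is argued against by monocyte markers taken as absent from neutrophils (median 1.31, from 0.49 for Fn1 to 2.33 for Chil3). That absence was assumed and is doubtful for Chil3. The others ran from 0.49 for Fn1 and 0.55 for F13a1 to 1.88 for Ly6c2. The higher level of these markers was part of the pattern as noticed, so it is no separate test. Ly6g had 0 reads in this library but only 4 in all 12, so its absence decides nothing. Its 28S share (2.13% against 0.341 and 0.425%) and mitochondrial share (3.18% against 4.60 and 4.36%) also differed from the other pools, and RNA quality and the makeup of that pool, by animals or sorting, were not tested and stay open.

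The counts were also taken over other splits of the libraries. For 3 libraries against 3 the splits are too few (10) for a share under 0.05. Where the real count is 0 every split gives as many, so the splits say nothing about chance by genotype in saline (10 of 10, real 0, highest other 0) and carrageenan (10 of 10, real 0, highest other 0), or for the difference of genotype effects (100 of 100 drawn, real 0, highest other 39). For carrageenan in Flox 1 of 10 gave as many (real 735, highest other 52) and in cKO 1 of 10 (real 270, highest other 0). Taking the cKO libraries as pairs by mouse numbers, 4 splits part 3 pairs, and the highest of the others gave 0.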

How the results depend on the processing

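The alternatives chosen after the data were seen were limma-voom, thinning, leaving out the pair of libraries apart (Flox saline 1-3 and cKO carrageenan 9-12) and leaving out libraries for the correlation. For the genotype counts, 0 in limma, arrayWeights gave 53 genes in saline, DESeq2 23 and thinning 1; in carrageenan arrayWeights gave 785, DESeq2 10 and leaving out the libraries apart 420 (that is, without cKO carrageenan 9-12). The estimation of the arrayWeights stopped before it converged in 4 fits. Leaving out each library gave 0 in saline throughout and 0 to 420 in carrageenan. Fabp5 in carrageenan was -2.29 with arrayWeights and -2.50 without the libraries apart, both then past the threshold (-2.50 to -1.62 over single libraries left out, adjusted p from 0.0346 to 0.971). Lyz2 in carrageenan was -1.45 with arrayWeights, -1.12 with DESeq2 and -1.40 without the libraries apart, also past it (-1.40 to -0.98, adjusted p from 0.00688 to 0.971). Fabp5 and Lyz2 in saline passed under none of the alternatives run.

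For carrageenan in Flox, 735 genes became 418 with no filter, 277 with only the 6 Flox libraries and 452 with thinning, and 334 (without Flox carrageenan 4-7) to 1073 (without Flox saline 8-10) over single libraries left out. In cKO, 270 became 139 with no filter, 91 without the trend, 3364 with arrayWeights, 733 in edgeR, 915 in DESeq2, 723 with only the 6 cKO libraries and 916 in limma-voom, and 84 (without cKO saline 1-4) to 507 (without Flox saline 1-3) over single libraries left out. The difference of genotype effects passed 0 genes in every omission of a library. With the replicate block, which treats libraries of the same mouse numbers as paired, 733 genes passed in Flox and 249 in cKO, 0 for the difference, and 14 and 16 lists in Flox and cKO. The block changed no call of a named gene other than the 5 cKO genes given in the report. The causes of the changed counts were not tested.

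Lists were lost mainly to the other set tests. With an estimated correlation 0 passed in saline and 0 in carrageenan for genotype (0 in each with fry), 1 for carrageenan in Flox and 6 in cKO; over single libraries left out the saline count went from 2 to 9. The correlation of genotype effects was 0.389 with a pseudocount of 5, 0.408 with a mean of at least 20, and 0.234 to 0.433 over single libraries left out.

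Of lists past the threshold, the cKO ribosomal list turned in its test direction, and the saline neutrophil markers in their median (-1.06 without Flox saline 1-3 to 0.42 without Flox saline 8-10). The saline monocyte markers, not past it with all libraries, had medians from -0.45 to 0.12. In saline Csf3r was -0.0011 with a pseudocount of 5, -0.093 with arrayWeights, -0.31 in edgeR, -0.26 in DESeq2 and in limma-voom and -0.044 without the libraries apart (-0.31 to 0.42 over single libraries). Trem1 was -0.15, -0.91, -1.10, -1.01, -0.47 and -1.12 in the same order (-1.12 to 1.13). The saline prostanoid list turned in fry (adjusted p = 0.905), and with single libraries left out the medians of interferon-stimulated genes were -0.081 to 0.84 and those of nociceptor mediators 0.088 to 0.75, where the test direction turned. In carrageenan PPAR targets and interferon-stimulated genes turned in fry (adjusted p = 0.984 for both), as did nociceptor mediators (0.935), and PPAR targets turned with a pseudocount of 5 (median 0.079). With single libraries left out, prostanoid genes ranged from -0.11 to 0.18, PPAR targets from -0.043 to 0.22, interferon-stimulated genes from -0.16 to 0.38, and ribosomal proteins for carrageenan in cKO from -0.14 to 0.56. The Fabp5 difference of effects was 0.035 with arrayWeights.

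Other named genes and lists are given as counts of alternatives, single libraries left out among them. For carrageenan in Flox, 49 called genes held in 1283 of 1321 alternatives and were no longer past the threshold in 38; in cKO, 47 held in 1098 of 1268 and lost the call in 170. Of 46 genes not called by genotype in carrageenan, 102 of 858 alternatives called 1, and of 44 in saline 22 of 812. Called lists lost the call in 29 of 224 alternatives for carrageenan in Flox, 19 of 240 in cKO, 21 of 51 by genotype in saline and 19 of 63 in carrageenan. Lists not called by genotype in saline gained a call in 4 of 63.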

Other observations

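Genes of oxidative defence, macrophage polarization and lipid signaling also changed with carrageenan. The cystine transporter Slc7a11 rose in Flox (3.47 ± 0.54) and cKO (2.67 ± 0.54), and so did glutathione reductase Gsr (1.60 ± 0.29 and 1.71 ± 0.29). Of 8 NRF2 response genes 3 rose and 1 fell in Flox (the same numbers adjusted over the list alone), and 2 rose in cKO (2 adjusted over the list alone). The list passed in neither (camera adjusted p = 0.327 and 0.144; in cKO the median was -0.21, the mean 0.37 and the test direction up). Among 11 genes of alternative activation, the chitinase-like Chil3 rose (3.43 ± 0.59 in Flox, 3.42 ± 0.59 in cKO), while Clec10a (-2.27 ± 0.40 and -2.49 ± 0.40) and Cd163 fell in both. In all 2 rose and 4 fell in Flox (3 and 4 adjusted over the list alone), and 1 rose and 3 fell in cKO (2 and 4). That list passed in neither genotype (0.455 and 0.613), with positive medians (1.30 and 0.54), positive means and a test direction of down. In the leukotriene pathway Alox5 (-1.83 ± 0.33) and the leukotriene receptor Cysltr1 (-1.74 ± 0.47) fell in Flox among 7 genes, also adjusted over the list alone, and Abhd12 fell among 7 endocannabinoid genes (-1.08 ± 0.26; lists 0.0842 and 0.0910). The inflammasome gene Nlrp3 rose in cKO (1.17 ± 0.26, 1 of 8) and was at 0.56 ± 0.26 in Flox; the difference of effects passed no gene.

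Among binding proteins related to Fabp5, 3 of 12 were measured well enough to test. Crabp2, which binds retinoic acid, rose with carrageenan in Flox (2.98 ± 0.84) and was at 0.97 ± 0.84 in cKO. The adipocyte form Fabp4 was 38.9 ± 8.69 against 12.6 ± 11.0 in Flox and 50.6 ± 9.99 against 21.0 ± 5.81 in cKO (carrageenan against saline), neither past the threshold in limma. Between genotypes in carrageenan Fabp4 was 47.9 ± 9.21 against 36.6 ± 8.14 (0.38 ± 0.31). Of cytotoxic lymphocyte genes Gzmb rose in cKO too (4.12 ± 0.74). Gzma had 0 reads in cKO saline and 4 in cKO carrageenan, against 1 and 35 reads in Flox (ratio interval 4.53 to 1095). Heme oxygenase Hmox1 was 6086 ± 4023 against 1622 ± 341 in carrageenan and 8150 ± 5958 against 2771 ± 1396 in saline (cKO against Flox), with overlapping groups in both. The cell-cycle genes Top2a (41.5 ± 6.82 against 8.97 ± 8.44) and Ccnb2 (13.9 ± 4.62 against 2.42 ± 0.913) were higher in cKO carrageenan. They passed adjusted over the list alone among 8 proliferation genes, though not over all genes (list adjusted p = 0.0623).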
